A study of Caenorhabditis elegans with 6 samples.

How the data were processed

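Messenger RNA from whole adult Caenorhabditis elegans was sequenced in 6 libraries, 2 for each of 3 strains. N2 is the standard laboratory strain and carries no transgene. WT (strain OD1463) and SIN (strain OD1175) are homozygous for csr-1(tm892), a deletion allele of csr-1, and for transgenes. The labels do not spell out SIN; from what is known of the study it stands for a slicing-inactive form of CSR-1, and WT for the normal form. Per the labels' protocols, each library came from 100 picked gravid adults grown at 20 °C on OP50 bacteria, and the WT and SIN worms were picked by their movement from among the progeny of balanced heterozygous mothers. Libraries were made from 500 ng of total RNA with a strand-specific, poly(A)-selecting TruSeq kit and read as 50-base single ends on a single lane, with an RNA integrity number of 7.9 to 8.9.

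The deposited table holds, per the file headers, a whole-number read count per gene and library for 46748 genes, of which 24486 had a count in at least 1 library. The submitters' processing notes name STAR, HTSeq, DESeq and DESeq2 without versions or roles, and the genome build WBcel235. The annotation release and the strand setting of the counting are not given in the sources used here, so a gene's reads cannot be separated from those of a gene overlapping it on either strand. The deposited RPKM (reads scaled to gene length and to the counted reads of the library) is 1 value per group, and in 100% of genes it equalled, to a relative tolerance of 1e-06, the mean of the libraries' RPKM recomputed from the deposited counts and gene lengths. The authors' log2 fold change and adjusted p-value for SIN against WT stand in the same table, per the file headers; which of the named tools made them is not given in the sources used here.

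The remaining deposited columns describe genes and not these samples. Per the file headers, the authors took 22G RNA reads per gene from a study by Claycomb as a normalized score whose scaling is not given in the sources used here. It is listed for 4133 genes, with a lowest value of 25. The authors' ratio of these reads to the group RPKM of N2 or of WT is deposited beside it. Per the file headers, 22G RNA in RPM, reads scaled to library size, came from a study by Conine, for a CSR-1 immunoprecipitate, and is listed for 5517 genes, all with at least 5 RPM. A deposited enrichment score over input, a fraction, ran from 0.667 to 0.969 for the same genes. The RPM of the input itself, 1 further column of the table, was not used here. Deposited classes mark genes as germline expressed (4643 genes), germline specific (1057 genes) and germline enriched (3061 genes). 22G RNAs are small RNAs, about 22 bases long and starting with G, that guide Argonaute proteins such as CSR-1 to transcripts.

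Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) after TMM scaling. The filterByExpr step, with a minimum count of 10 and a smallest total of 15, left 15404 genes; it removed at most 0.0476% of the counts of any library. All 6 libraries entered a single robust fit with 3 group means, which left 3 residual degrees of freedom, with a prior of 3.58. The biological coefficient of variation was 0.219. P-values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, at a threshold of 0.05. "Rose" and "fell" below refer to genes past that threshold. Levels are counts scaled to library size with TMM (CPM), as mean ± SD of 2 libraries, and fold changes are those of the fit. A fold against a group without a read was replaced by a lower bound, from 3 counts over the whole group, and a ratio against 1 to 3 counts is given with its 95% exact counting interval; both cover counting error only. The scaling assumes that most transcripts did not change, and sequencing reads here measure shares of mRNA, not amounts per worm.

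The 28 gene lists, the rule for named genes, the tests of genes, lists and classes, and the alternatives, apart from 2 named in the closing section, were written before the data were examined. The tests of explanations in the closing section were written later, when the patterns they concern had been seen. After csr-1, klp-7 and unc-119, the rule takes called genes whose libraries do not overlap between the groups and whose higher group has a mean of at least 2 CPM. Of these it names the 5 largest rises and falls and the 10 largest among genes with a gene-class symbol in SIN versus WT, and 3 and 5 in the other comparisons. For each list the rule allows the 4 members with the smallest p as examples. The lists cover csr-1 and its cofactors; other Argonautes and small RNA factors; P granule components; oocyte and maternal RNA regulators; kinetochore and spindle checkpoint; spindle, centrosome and cytokinesis; cell cycle and DNA replication; meiotic chromosome factors; sperm genes; major sperm protein genes; replication-dependent histone genes; eggshell and egg activation; vitellogenins; zygotic genes of the early embryo; markers of intestine, body wall muscle, pharynx and neurons; cuticle and hypodermis genes; collagen genes; pathogen response genes; heat shock and stress chaperones; oxidative, metal and xenobiotic stress; lipid metabolism; cell death and DNA damage; cytosolic ribosomal proteins; proteasome subunits; and the mitochondrial respiratory chain. 8 listed names matched no gene of the table and were left out. Examples outside these rules, such as the members of gene-name families in the closing section, were chosen after their values were seen. Members were matched by the table's own symbols or by gene ID through a reference name table.

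Lists and deposited classes were tested with limma's camera at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 28 lists or over the classes of a comparison. The same test was repeated with an estimated correlation, under which no list of any comparison was called. Calls were lost there even where the estimated correlation lay below the preset. For histone genes in SIN versus WT it was -0.018, and camera's adjusted p went from 0.0019 to 0.83. For csr-1 and its cofactors in SIN versus N2 it was -0.14, and the adjusted p went from 0.024 to 0.87. A call lost under this setting thus does not decide for or against a list. Class medians were also placed among those of 10000 random gene lists matched on mean expression in 50 bins. The alternatives were DESeq2 1.42.0, other scalings, other filters, the replicate number as a block, a test against a 1.5-fold change, fits on 4 libraries, the fry test for lists and the omission of each library. Coordinates and biotypes come from a reference annotation of WBcel235, matched by gene ID for 99.2% of tested genes.

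The testing step was run on counts simulated from the real means and library sizes, with 200 genes changed. With each gene's own spread, 32.8% of genes changed 2-fold and 62.1% of those changed 4-fold were recovered in SIN versus WT over 8 runs of 14966 to 15026 genes, but 15.9% of the calls were false. In SIN versus N2 the recovered shares were 33.4% and 67.6% with 13.7% of calls false, and in WT versus N2 they were 36.9% and 61.9% with 15.9% of calls false. Of genes changed 1.5-fold, 7.65%, 7.09% and 6.9% were recovered in these comparisons. When the spread followed its trend with expression, 4.83%, 4.25% and 3.36% of the calls were false. With 4000 genes changed in SIN versus WT, 3.57% of the calls were false and 55.7% of the changes were recovered, over 4 runs. Adjusted p-values were thus too small where 200 genes changed and each gene had its own spread, and not where the spread followed the trend; which of these is nearer to the WT versus N2 data is not known. The list step recovered a 50-gene list changed 1.5-fold in 8 of 8 runs and called 0 of the 27 unchanged lists in each run, on 15404 genes. Genes in that simulation varied independently and the lists were random. The result thus does not cover lists whose members vary together, such as major sperm protein and ribosomal protein genes (estimated correlations 0.97 and 0.88).

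Depth ranged from 33739391 to 44962816 counts per library, so that 3 counts correspond to 0.0667 to 0.0889 CPM before scaling. The labels call the libraries replicates without saying that they came from separate cultures; p-values therefore measure only the spread between these libraries, which may be technical. The authors' fold change and p-value were not used for any test here. The raw reads, the transgene sequences and the published small RNA libraries were not used here.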

Results

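To ask how an Argonaute of the germline shapes messenger RNA levels, the study compared adult hermaphrodites of 3 strains. CSR-1 is an Argonaute protein that cuts RNA paired to its 22G small RNAs. N2 carries no transgene. The WT and SIN strains are homozygous for the csr-1 deletion tm892 and carry transgenes. The labels give only those abbreviations; from what is known of the study, SIN has a slicing-inactive csr-1 transgene and WT the normal form. The N2 libraries held 44962816 and 42435429 counts, the WT libraries 42126710 and 33739391, and the SIN libraries 39865531 and 34654600. The labels do not state whether replicates came from separate cultures, so p-values here measure only the spread between these libraries, which may be technical. Between 18745 and 20674 genes had at least 1 read in a library.

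The SIN libraries lay apart from the others on the main axis of variation, which held 52.9% of the variance of log2 CPM. They were at 72.3 and 76.1 on that axis, and the N2 and WT libraries were between -45.9 and -21.2. N2 replicate 1 stood apart on the next axis, which held 26.6% of the variance, at 72.9 against -7.13 for N2 replicate 2. Across genes, log2 CPM correlated with Pearson's r = 0.99 between the SIN libraries, 0.9888 between the WT libraries and 0.9715 between the N2 libraries. Both libraries of every group differed by more than sampling noise, with a lowest chi-square per degree of freedom of 8.944. Vitellogenin transcripts, which encode yolk proteins made in the intestine, took 3.89% to 5.55% of the counts, and the 10 most abundant genes took 6.83% to 8.16%.

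The transcript of csr-1 itself was far more abundant in SIN. It reached 3110 ± 280 CPM (SD, n = 2) in SIN, 649 ± 19 CPM in WT and 461 ± 22 CPM in N2. By library the values were 445 and 476 CPM in N2, 662 and 636 CPM in WT and 2910 and 3310 CPM in SIN. SIN exceeded WT by 4.79-fold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000223). The 1.41-fold difference of WT from N2 did not pass (adjusted p = 0.122). The table has 1 row for csr-1 (chromosome IV, 7957267 to 7962157, WBcel235), which overlaps frpr-10 on the same strand, so reads of a transgene and of the remaining chromosomal sequence were not separated and a base change would not show in these counts.

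A still larger difference was seen for klp-7, which encodes a kinesin that shortens microtubules and is needed for spindle assembly (chromosome III, 10805925 to 10811001). Its level was 2120 ± 52 CPM in SIN, 236 ± 0.4 CPM in WT and 161 ± 2.7 CPM in N2 (SD, n = 2 each), an 8.98-fold rise over WT (adjusted p = 5.94e-05) and a 13.1-fold rise over N2 (adjusted p = 2.72e-05). The authors' deposited table lists log2 fold changes of 2.21 for csr-1 and 3.12 for klp-7, beside 2.26 ± 0.12 and 3.17 ± 0.1 (SE) in the fit used here; for some other genes its values are far smaller, as given further on. A gene often used to select transgenic worms, unc-119 (chromosome III, 10902641 to 10908935), was lower in both transgenic strains. It had 8.03 ± 0.24 CPM in SIN, 8.16 ± 0.34 CPM in WT and 16.8 ± 1.7 CPM in N2. The difference passed the test for SIN (2.09-fold lower, adjusted p = 0.00743) and not for WT (2.06-fold lower, adjusted p = 0.0763). The SIN call for unc-119 was lost without SIN replicate 1 or 2 (adjusted p = 0.0685 and 0.0598). In WT versus N2, csr-1, klp-7 and unc-119 did pass with DESeq2 (adjusted p = 0.000187, 2.19e-08 and 2.3e-05), and without N2 replicate 1 (0.0375, 0.00903 and 0.0198) or N2 replicate 2 (0.00444, 0.00171 and 0.00221).

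**Figure D1:**
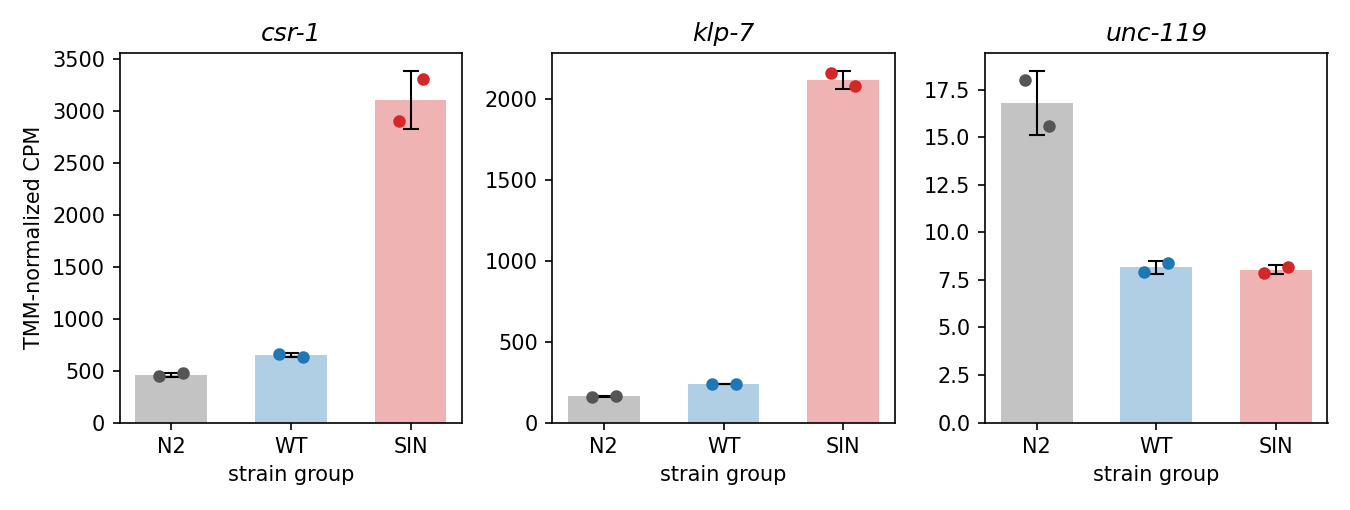
Levels of csr-1, klp-7 and unc-119 in TMM-normalized CPM (vertical axes) in each strain (horizontal axes); bars are means, error bars SD and points the 2 libraries of a strain. In SIN, csr-1 and klp-7 reached 3110 and 2120 CPM, above every N2 and WT library, and unc-119 stood at 8.03 CPM, near the 8.16 CPM of WT and below the 16.8 CPM of N2.

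The comparison of SIN with WT sets 2 strains with the same chromosomal csr-1 allele against each other. In SIN, 1871 of 15404 genes rose and 2051 fell. Rises were larger than falls, with a median of 2.58-fold against 1.55-fold among called genes, and 1180 rises and 327 falls were at least 2-fold. Spindle, meiotic chromosome, sperm and pathogen response genes were among those that rose, and genes for ribosomal proteins, proteasome subunits and the respiratory chain were among those that fell. The split depended on scaling: with upper-quartile scaling, which moved the median log2 fold change of all genes from 0.04 to 0.17, 2329 genes rose and 1227 fell, so that 65.5% of the calls were rises against 47.7%.

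The largest rises by the rule for named genes were in transcripts almost absent from WT. The collagen gene col-183 had no read in WT and 2.58 ± 2 CPM in SIN, at least 65.9-fold higher (adjusted p = 0.00935). The lysozyme gene ilys-3 had 1 read in the WT libraries and 3.5 ± 0.054 CPM in SIN, a ratio of 257 (counting interval 45.8 to 10200, adjusted p = 0.0174), and the neuropeptide-like gene nlp-39 a ratio of 234 (41.6 to 9270, adjusted p = 0.0462). The genes F56D6.9, which overlaps oac-21 on the same strand, and F56D6.8 had 40.5 ± 21 and 40.3 ± 20 CPM in SIN against 0.177 ± 0.16 CPM in WT each, 212-fold and 211-fold higher (adjusted p = 0.0147 and 0.0233). Next came dct-8 (72-fold), dhs-26 (65.4-fold), cnc-6 (50-fold), ora-1 (39.9-fold) and dot-1.2 (25.9-fold), with spp-9 and scl-20 at ratios of 79 (21.5 to 658) and 63.1 (21.3 to 308) over 2 and 3 reads in WT. F56D6.9, F56D6.8 and dct-8 are neighbours between 3892327 and 3895506 on chromosome IV. Their SIN levels were near-equal, at 55.3, 54.4 and 60 CPM in replicate 1 and 25.6, 26.2 and 27.6 CPM in replicate 2. They may share reads, so they may not be separate rises. Of the genes named here, dot-1.2 encodes a relative of a histone methyltransferase, and spp-9, cnc-6 and ilys-3 belong to antimicrobial gene families. Adjusted p ran from 0.00257 for dot-1.2 to 0.0462 for nlp-39 across the rises.

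Several of these genes also differed between the N2 libraries, and F56D6.8, ilys-3, nlp-39, dct-8, dhs-26, scl-20, cnc-6 and ora-1 did not pass in SIN versus N2 (adjusted p = 0.111, 0.146, 0.317, 0.112, 0.959, 0.11, 0.13 and 0.0668). Their log2 fold changes there were 2.97, 2.04, 1.84, 2.25, -0.1, 3.1, 2.87 and 3.21. In WT versus N2, F56D6.8, dct-8 and dhs-26 had log2 fold changes of -4.75, -3.92 and -6.13, none past the test. For F56D6.8, ilys-3, nlp-39, dct-8 and dhs-26, both WT libraries lay below both N2 libraries. Part of their rise over WT thus goes with a low WT level. For scl-20, cnc-6 and ora-1, N2 replicate 2 was below both WT libraries, at 0, 0.0742 and 0.717 CPM. Only N2 replicate 1 was above WT for these genes, at 0.562, 2.7 and 8.62 CPM. Expression of dhs-26, which overlaps ZK816.1 on the other strand, was 54.8 CPM in N2 replicate 1 and 2.7 CPM in N2 replicate 2, against 30.3 and 23.4 CPM in SIN. Levels of dct-8 were 14.9 and 3.36 CPM, of F56D6.8 9.64 and 0.594 CPM, of ora-1 8.62 and 0.717 CPM, and of cnc-6 2.7 and 0.0742 CPM in N2 replicates 1 and 2.

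The largest falls were smaller. C08E8.3 fell 14.4-fold, from 2.97 ± 0.36 to 0.201 ± 0.087 CPM (adjusted p = 0.00367); its N2 levels of 0.0865 and 0.148 CPM are as low as those of SIN, and WT is the strain that departs. nhr-181, a nuclear hormone receptor gene, fell 12-fold, from 5.29 ± 0.33 to 0.436 ± 0.025 CPM (adjusted p = 0.0014). The pseudogene ZK637.6 fell 9.7-fold (adjusted p = 0.000459) and C50E3.11 fell 7.61-fold, from 29.4 ± 0.086 to 3.87 ± 0.095 CPM (adjusted p = 0.000169). The wee-1.1 gene, a relative of a cell cycle kinase that overlaps exc-7 on the other strand, fell 9-fold (adjusted p = 0.0134). The remaining falls named by the rule were gst-16 (5.5-fold), the pseudogene skr-11 (4.89-fold), tba-9 (4.76-fold), fbxc-32 (4.29-fold), set-20 (4.15-fold), the pseudogene bath-11 (4-fold), tpk-1 (3.95-fold) and nhr-190 (3.74-fold), with adjusted p between 0.0027 and 0.029. Of the named falls, C08E8.3, skr-11 and tba-9 did not pass in SIN versus N2 (adjusted p = 0.302, 0.0522 and 0.163).

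Many of these calls were lost when a WT or SIN library was left out. Such a fit leaves a lone library in a group, so the shared spread rests more on the other groups, N2 included. The N2 libraries differed most between replicates (Pearson's r = 0.9715, against 0.99 for SIN and 0.9888 for WT). With only the 4 SIN and WT libraries, 6521 genes were called, against 3922 with all 6. A lost call thus does not show that a change rested on a particular library. Among the genes named by the rule, dot-1.2, C08E8.3, nhr-181, ZK637.6, C50E3.11, gst-16 and fbxc-32 stayed past the test whichever library was left out. Calls were lost for col-183 without WT replicate 1 or SIN replicate 1 (adjusted p = 0.0626 and 0.0511), for set-20 without SIN replicate 1 (0.0512) and for tpk-1 without WT replicate 1, WT replicate 2 or SIN replicate 2 (0.0613, 0.0521 and 0.0551). For the other 15 genes the call was lost with each of the WT and SIN libraries left out. The highest adjusted p was then 0.249 and 0.235 without WT replicates 1 and 2, and 0.175 and 0.176 without SIN replicates 1 and 2. Several of these genes kept log2 fold changes close to the reported ones, such as ora-1 (5.01 to 5.65, against 5.32), dhs-26 (5.83 to 6.2, against 6.03) and tba-9 (-2.44 to -2.05, against -2.25). RLE scaling also ended the call of nlp-39 (adjusted p = 0.0505). The test against a 1.5-fold change, which asks for more, ended 9 of these calls (adjusted p = 0.0507 to 0.129).

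Folds of other named genes moved with a library. Without WT replicate 1, dct-8 was 280-fold higher, the ratios of F56D6.9 and F56D6.8 over 2 reads were 678 (188 to 5600) and 675 (187 to 5570), and ilys-3, nlp-39 and spp-9, with no WT read left, were at least 38-fold, 34.5-fold and 23.4-fold higher. Without WT replicate 2 the folds were 135 for F56D6.9, 134 for F56D6.8 and 43.1 for dct-8, and the ratios 143 (25.5 to 5680) for ilys-3, 130 (23.1 to 5160) for nlp-39 and 44 (12 to 366) for spp-9. The fold of dot-1.2 was 17.1 and 46.9 without WT replicates 1 and 2. Without SIN replicate 1, F56D6.9 was 135-fold, F56D6.8 138-fold and dct-8 45.9-fold higher and wee-1.1 17.8-fold lower, and the ratios of nlp-39 and scl-20 were 117 (20.2 to 4700) and 35.5 (11.5 to 178). The bound of col-183 was at least 28.7-fold without SIN replicate 1 and at least 97.8-fold without SIN replicate 2.

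Genes for the small RNA machinery rose more often than they fell. Of the cofactors of CSR-1, the RNA-dependent RNA polymerase gene ego-1 rose 2.09-fold, from 178 ± 3.1 to 371 ± 7.5 CPM (adjusted p = 0.000866), whereas the 1.17-fold difference of drh-3 (adjusted p = 0.0946) and the ekl-1 level of 122 ± 13 CPM against 130 ± 3.6 CPM (adjusted p = 0.525) did not pass. With csr-1, 2 of the 4 tested members rose, or 3 adjusted over the list alone (camera adjusted p = 0.086). Of 48 other Argonaute and small RNA factors, 19 rose, 8 fell and 21 did not pass (22 and 9 adjusted over the list alone; camera adjusted p = 0.071). By fry both lists passed as higher (adjusted p = 0.0016 and 0.014). The list of csr-1 and its cofactors includes csr-1 itself, whose reads are not separated from those of a transgene. Its result thus does not show that the cofactors rose as a group. Nuclear RNAi factor nrde-2 rose 8.5-fold, from 195 ± 1.1 to 1660 ± 86 CPM (adjusted p = 5.94e-05). The mutator genes mut-14 and mut-15 rose 3.71-fold and 2.79-fold, and ZK1067.2, known as znfx-1, rose 3.03-fold. P granules are condensates of the germline. Of their genes, 6 of 17 rose and 6 fell (6 and 7 adjusted over the list alone; median -0.13 and mean 0.16, camera direction down, adjusted p = 0.97; 7 and 4 with a median of 0.01 under upper-quartile scaling), the rises including the helicase genes glh-4 (3.29-fold), glh-1 (3.05-fold) and glh-2 (2.03-fold).

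Cell division and meiotic genes made up 4 of the lists. Among spindle, centrosome and cytokinesis genes, 23 of 50 rose and 9 fell (24 and 9 adjusted over the list alone). The list passed the camera test (adjusted p = 0.00096) but not with an estimated correlation (adjusted p = 0.92). Apart from klp-7, gpr-1 rose 11.3-fold, gpr-2 8.5-fold and klp-15 5.31-fold (adjusted p = 5.94e-05, 5.94e-05 and 0.00011); gpr-1 and gpr-2, which position the spindle, are near-identical copies, as are klp-15 and klp-16, so that reads may be divided between them. Of 32 meiotic chromosome factors 20 rose and 3 fell (22 and 5 adjusted over the list alone; camera adjusted p = 0.00096, adjusted p = 0.92 with an estimated correlation). Rises included the checkpoint kinase gene chk-2 (12.9-fold, from 10.9 ± 0.065 to 141 ± 23 CPM), htp-1 (5.04-fold, with a close copy in htp-2) and the crossover gene msh-5 (1.96-fold). Kinetochore and checkpoint genes showed 11 rises and 4 falls among 28 (11 and 5 adjusted over the list alone; camera adjusted p = 0.4). The centromeric histone gene hcp-3, which overlaps F58A4.6 on the other strand, rose 3.62-fold to 633 ± 35 CPM, spdl-1 rose 4.37-fold and cls-2 6.16-fold. Cell cycle and DNA replication genes moved both ways, with 7 rises and 11 falls among 38 (9 and 12 adjusted over the list alone; median -0.03, camera adjusted p = 0.4), or 9 and 8 with upper-quartile scaling (median 0.1); cdk-1 rose 2.02-fold and the helicase subunit gene mcm-4 fell 2.12-fold.

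Genes of germ cell fate and gametes were divided. Of 30 oocyte and maternal RNA regulators, 7 rose and 8 fell (8 and 11 adjusted over the list alone; median -0.09 and mean 0.26, camera direction down, adjusted p = 0.63), and 8 rose and 2 fell with upper-quartile scaling (median 0.04). The rises included fog-3, which directs germ cells to sperm fate (19.6-fold, from 2.35 ± 0.34 to 46.4 ± 13 CPM, adjusted p = 0.000825), fog-1 (3.6-fold) and the close copies fbf-1 and fbf-2 (6.23-fold and 4.37-fold). Sperm genes had 9 rises and 1 fall among 33 (9 and 1 adjusted over the list alone), with a median log2 fold change of 1.29 (camera adjusted p = 0.00014, adjusted p = 0.92 with an estimated correlation, and 0.083 by fry). Their mean relative log2 level was -1.07 in WT replicate 1 and 0.33 in WT replicate 2, against 0.92 and 1.51 in SIN. Those that rose included fer-1 (20.8-fold, to 3.75 ± 0.1 CPM), spe-15 (3.33-fold) and gska-3 (4.03-fold). Of the 24 tested major sperm protein genes, which are near-identical and share reads, 0 rose and 0 fell, adjusted over all genes or over the list alone, with a median of 0.61 (camera adjusted p = 0.29); their mean level relative to the other libraries was -1.78 in WT replicate 1 and 1.67 in WT replicate 2, on the log2 scale. Of 16 eggshell and egg activation genes 4 rose and 7 fell, adjusted over all genes or over the list alone (camera adjusted p = 0.21). The chitin synthase gene chs-1 fell 1.67-fold, and the close copies egg-4 and egg-5 rose 2.15-fold and 1.61-fold. None of the 6 vitellogenin genes, which also share reads, passed the test, adjusted over the list alone included (camera adjusted p = 0.63); vit-2 had 15700 ± 2300 CPM in SIN and 12500 ± 290 CPM in WT.

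**Figure D2:**
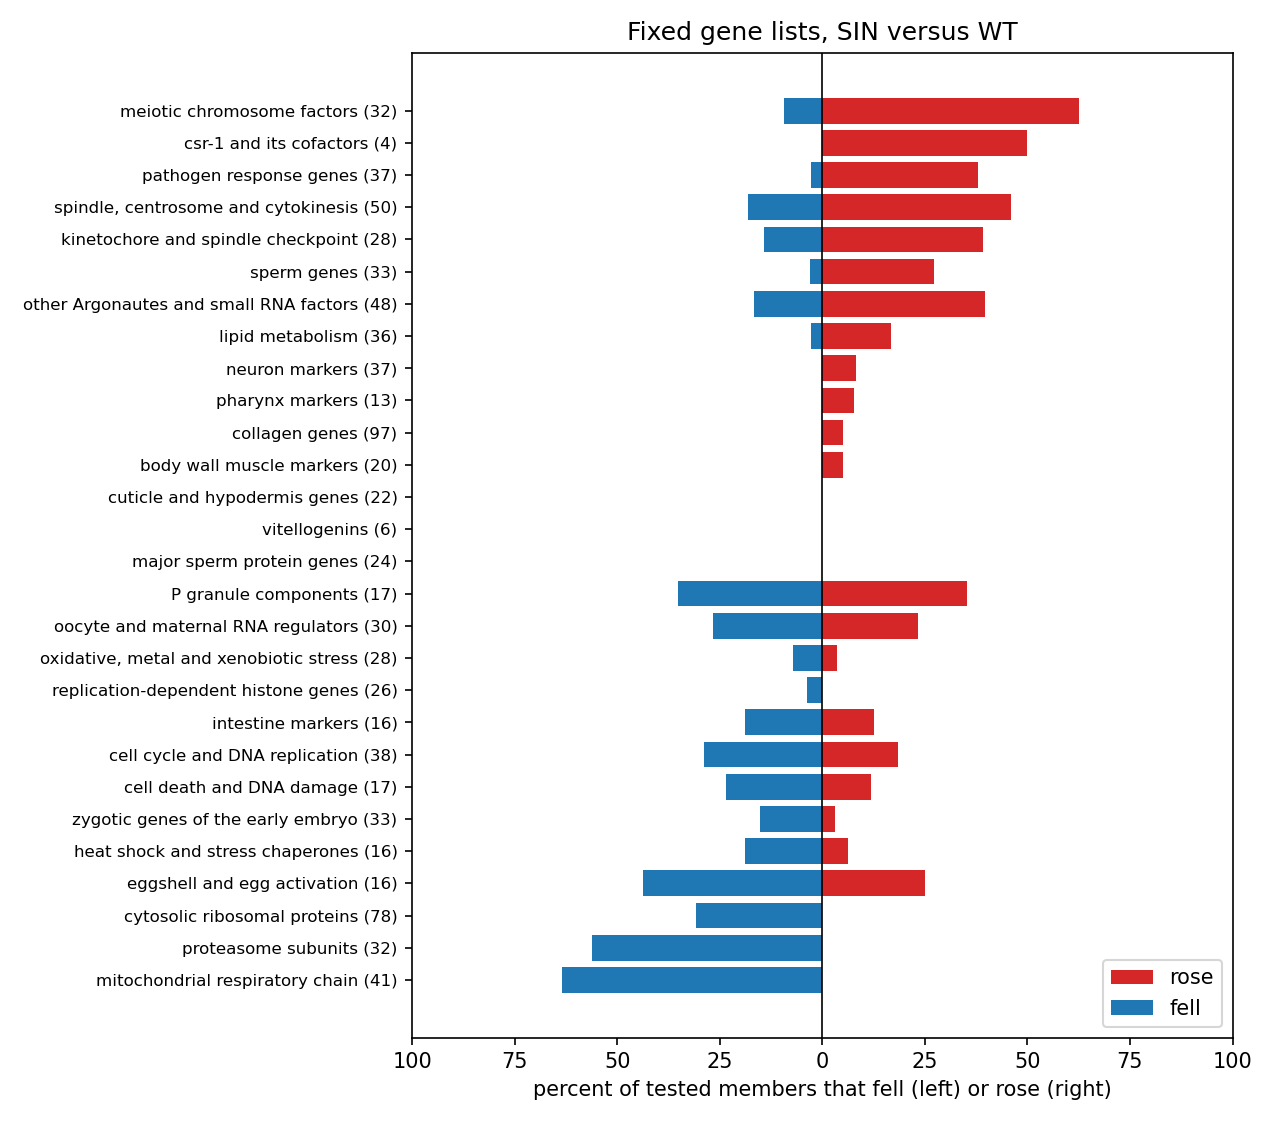
Share of the tested members of each of the 28 gene lists that rose (right, red) or fell (left, blue) in SIN versus WT, in percent on the horizontal axis. The number of tested members is in brackets, and lists are ordered by the share that rose minus the share that fell. Of 32 meiotic chromosome factors 20 rose and 3 fell, and of 41 respiratory chain genes 26 fell and none rose under TMM scaling; under upper-quartile scaling these counts were 22 and 2, and 12 and 0.

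Genes for protein synthesis, protein degradation and respiration were lower in SIN. Of 78 cytosolic ribosomal protein genes 24 fell and none rose, or 62 adjusted over the list alone, with a median log2 fold change of -0.63 (camera adjusted p = 1.5e-11). Their examples rpl-12, rps-29 and rpl-1 fell 1.81-fold, 1.56-fold and 1.56-fold. Of 41 respiratory chain genes 26 fell and none rose (37 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 1.6e-10); asg-1, a subunit gene of the ATP synthase, fell 1.95-fold, from 206 ± 14 to 106 ± 1.2 CPM. Of 32 proteasome genes 18 fell and none rose (22 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 2.7e-05), pbs-7 falling 1.58-fold. For each of these lists the adjusted p was 0.92 with an estimated correlation, and by fry it was 0.17, 0.093 and 0.11. Upper-quartile scaling left 2 ribosomal, 12 respiratory and 6 proteasome genes that fell, and 1 proteasome gene rose, with medians of -0.5, -0.49 and -0.3. Ribosomal protein genes were also lower in N2 replicate 1 than in N2 replicate 2, at -0.21 against 0.39 relative to the mean of the 6 libraries on the log2 scale. The SIN libraries stood at -0.41 and -0.28, and the WT libraries at 0.23 and 0.29.

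Replication-dependent histone genes, many of which are near-identical and whose transcripts mostly lack the poly(A) tails that the kit selects, passed the camera test as lower (median -0.45, adjusted p = 0.0019, adjusted p = 0.83 with an estimated correlation). Only his-61 among 26 tested members fell, 2.23-fold, adjusted over all genes or over the list alone. Zygotic genes of the early embryo had 1 rise and 5 falls among 33 (0 and 2 adjusted over the list alone; camera adjusted p = 0.13), the falls including ceh-51 (10.2-fold, from 1.32 ± 0.13 to 0.123 ± 0.096 CPM) and sdz-31 (18.2-fold), both at low levels.

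Of 37 pathogen response genes 14 rose in SIN and 1 fell (20 and 2 adjusted over the list alone), with a median log2 fold change of 1.07 (camera adjusted p = 0.0028, adjusted p = 0.92 with an estimated correlation, and 0.093 by fry). Besides ilys-3 and cnc-6, cnc-2 rose 8.81-fold to 33.1 ± 11 CPM, spp-12 9.57-fold and clec-67 2.63-fold, and spp-18 fell 3.41-fold. The list also differed within N2: its mean relative log2 level was 0.28 in N2 replicate 1 and -0.57 in replicate 2, against 0.91 and 0.58 in SIN and -0.51 and -0.7 in WT. Of 36 lipid metabolism genes, 6 rose and 1 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.35), among them cpt-3 (15.8-fold) and the desaturase gene fat-5 (4.88-fold). With 41.6 and 66.7 CPM in N2 and 60.9 and 48.8 CPM in SIN, fat-5 stood apart in WT (11.2 CPM in each library; WT versus N2 adjusted p = 0.0502), and spp-12, phat-6, hsp-3 and his-61 did not pass in SIN versus N2 either (adjusted p = 0.231, 0.765, 0.0528 and 0.213). Heat shock genes had 1 rise and 3 falls among 16 (1 and 4 adjusted over the list alone, camera adjusted p = 0.13). The chaperone genes hsp-1, hsp-3 and daf-21 fell 1.79-fold, 1.8-fold and 1.9-fold. Of 28 oxidative, metal and xenobiotic stress genes 1 rose and 2 fell, adjusted over all genes or over the list alone (camera adjusted p = 0.97), gst-7 falling 2.28-fold. Cell death and DNA damage genes had 2 rises and 4 falls among 17 (5 and 6 adjusted over the list alone; median -0.02 and mean 0.03, camera adjusted p = 0.61; 4 and 4 with a median of 0.12 under upper-quartile scaling), with cep-1, the worm p53 gene, rising 1.74-fold and the checkpoint gene hus-1 falling 1.82-fold.

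Markers of somatic tissues gave few calls. Intestine markers had 2 rises and 3 falls among 16 (3 and 3 adjusted over the list alone; median -0.3, mean 0.12), or 3 and 0 with upper-quartile scaling. The esterase gene ges-1 rose 1.46-fold and the membrane linker gene erm-1 fell 1.25-fold. Muscle markers had 1 rise among 20, unc-45 (1.23-fold), and pharynx markers 1 rise among 13, phat-6 (1.79-fold), with a median of -0.1, or 0.04 under upper-quartile scaling; adjusted over the list alone neither list kept a call. Neuron markers had 3 rises among 37, or 2 adjusted over the list alone: unc-31 (9.14-fold, from 2.94 ± 0.34 to 26.9 ± 3.7 CPM, adjusted p = 0.000538), cat-2 (4.85-fold) and unc-104 (1.61-fold), which act in vesicle release, dopamine synthesis and vesicle transport. None of 22 cuticle and hypodermis genes passed, adjusted over the list alone included (median 0.64), and 5 of 97 collagen genes rose with none falling (4 adjusted over the list alone), including col-63 (22.2-fold) and col-38 (2.48-fold). Camera adjusted p for intestine, muscle, pharynx, neuron, cuticle and collagen lists was 0.4, 0.56, 0.59, 0.4, 0.54 and 0.63. Upper-quartile scaling also gave 23 rises and 4 falls among small RNA factors, 27 and 4 among spindle, 11 and 2 among kinetochore, 4 and 4 among eggshell, 1 and 2 among zygotic, 1 and 2 among heat shock, 1 and 1 among oxidative stress and 6 and 0 among lipid genes.

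The authors' deposited table gives an adjusted p for 15160 genes, of which 4495 pass 0.05, 1937 higher and 2558 lower in SIN. Of the 3922 genes called here, 3715 are called in the authors' deposited table, all in the same direction; 116 are not called there and 91 have no adjusted p there. For the largest rises the authors' deposited table has much smaller log2 fold changes: 1.31 for F56D6.9 against 7.73 here, 0.99 for F56D6.8 against 7.72, 0.88 for cnc-6 against 5.64, and 0.69 for dhs-26 against 6.03, which is not called there (adjusted p = 0.13). How the deposited fold changes were estimated is not given in the sources used here, so they may be an unlike measure. The number of calls changed with the libraries used. With N2 replicate 1 or 2 left out, 3231 and 3244 genes rose and 3362 and 3375 fell. With WT replicate 1 or 2 left out, 252 and 328 rose and 89 and 144 fell. With SIN replicate 1 or 2 left out, 334 and 430 rose and 306 and 145 fell. Against a change of at least 1.5-fold, 480 genes rose and 155 fell.

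Small RNA levels published by others and deposited beside the counts divided the germline transcripts. The top quintile of listed genes by 22G reads (824 genes, Claycomb) had 372 rises and 59 falls in SIN versus WT and a median log2 fold change of 0.27, above all 10000 random lists matched on expression, 95% of which lay between -0.17 and -0.11 (camera adjusted p = 1e-09, adjusted p = 0.37 with an estimated correlation). The top quintile by 22G RNA in CSR-1 immunoprecipitates (1051 genes, Conine) had 401 rises and 146 falls and a median of 0.22 (adjusted p = 4.3e-05, and adjusted p = 0.37 with an estimated correlation). By contrast, the top quintile by the deposited enrichment score of the immunoprecipitate over input had 122 rises and 336 falls and a median of -0.25 (adjusted p = 3.5e-06, and adjusted p = 0.41 with an estimated correlation), or 161 rises and 193 falls with upper-quartile scaling. csr-1 and klp-7 are both on the Claycomb list, with 1060 and 1820 22G reads.

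Divided by transcript level, 22G reads ordered the genes much as the reads alone did. By the reads alone, the median log2 fold change of SIN versus WT was -0.45 in the lowest decile and 0.46 in the highest. The share of genes that rose was 1.46% and 57.8%. By the ratio of 22G reads to N2 RPKM, the median log2 fold change of SIN versus WT ran from -0.5 in the lowest decile (412 genes) to 0.5 in the highest, the share of genes that rose from 0.243% to 58% and the share that fell from 54.6% to 2.18%. In WT versus N2 the same deciles had medians of 0.12 and 0.04. The top quintile by this ratio had 377 rises and 43 falls among 823 genes (median 0.31, adjusted p = 1.6e-11, and adjusted p = 0.37 with an estimated correlation), and the top quintile by the ratio to WT RPKM 359 and 35 (median 0.28, adjusted p = 8.5e-11, and adjusted p = 0.37 with an estimated correlation). The authors made these ratios from libraries of this study: the ratio to WT RPKM shares the WT libraries with SIN versus WT, and the ratio to N2 RPKM shares the N2 libraries with WT versus N2, so neither is independent of that comparison's fold changes.

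**Figure D3:**
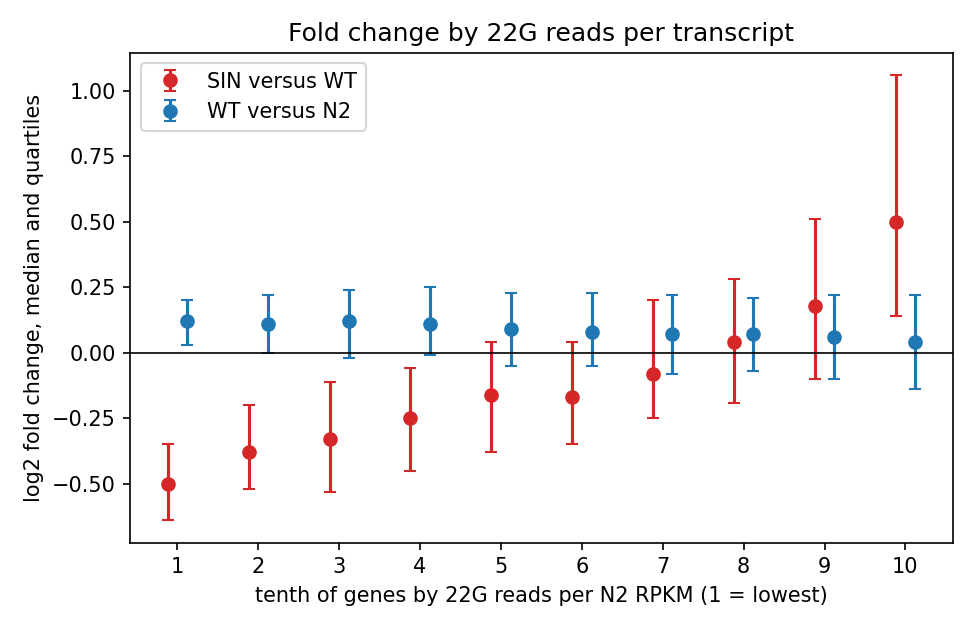
Median log2 fold change (points) with quartiles (bars) on the vertical axis in deciles of genes ordered by 22G reads per N2 RPKM on the horizontal axis, for SIN versus WT (red) and WT versus N2 (blue). The SIN versus WT medians run from -0.5 in the lowest decile to 0.5 in the highest, and those of WT versus N2 from 0.12 to 0.04.

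For the whole lists of 22G targets the balance of rises and falls depended on scaling. With TMM scaling, the 4114 Claycomb genes had 599 rises and 1096 falls (median -0.16, camera adjusted p = 1.2e-05, adjusted p = 0.41 with an estimated correlation), at percentile 20.8 of random lists matched on expression. The 5253 Conine genes had 873 rises and 1285 falls (median -0.11 and mean 0.21, adjusted p = 0.0084 as lower, and adjusted p = 0.48 with an estimated correlation), at percentile 23.9; without SIN replicate 2 the adjusted p was 0.13. Germline expressed genes had 516 rises and 1340 falls among 4624 (median -0.22), and germline specific genes 75 and 438 among 1056 (median -0.36), both below every random list (adjusted p = 1e-10 and 1.2e-12, and adjusted p = 0.37 with an estimated correlation for each). Germline enriched genes had 566 rises and 613 falls among 2713, with a median of 0, a mean of 0.43 and a camera direction of down (adjusted p = 0.87, and adjusted p = 0.96 with an estimated correlation). Their median lay above every matched random list, 95% of which fell between -0.07 and -0.02. With upper-quartile scaling the medians were -0.09 for germline expressed, -0.22 for germline specific, 0.13 for germline enriched, -0.03 for Claycomb and 0.03 for Conine genes, so the last turned from lower to higher. The balance of calls turned too: 841 Claycomb genes rose and 606 fell, 1120 Conine genes rose and 725 fell, and 668 germline enriched genes rose and 400 fell, while 729 germline expressed genes rose and 783 fell and 112 germline specific genes rose and 231 fell. Against N2, with TMM scaling, SIN had 760 rises and 797 falls among Claycomb genes, 1081 and 881 among Conine genes and 716 and 452 among germline enriched genes. Germline expressed genes had 629 and 1052, and germline specific genes 121 and 275 (median -0.25). Median log2 fold changes of germline expressed and germline specific genes in WT versus N2 were 0.09 and 0.13. Part of their falls against WT thus goes with a higher WT level.

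Set against N2, the SIN strain had 1899 genes that rose and 2043 that fell. Rises had a median of 2.49-fold and falls of 1.63-fold, and 1162 and 616 were at least 2-fold. The largest rises were those of F21F3.3 (74.2-fold, from 0.0958 ± 0.074 to 7.15 ± 0.18 CPM, adjusted p = 0.00395), alg-4, an Argonaute gene of the male germline (69.4-fold, to 4.29 ± 1.7 CPM, adjusted p = 0.0208) and F23B2.10 (65-fold, to 3.22 ± 1.4 CPM, adjusted p = 0.00191). Among genes with a gene-class symbol they were followed by dot-1.2 (44.5-fold), col-183 (42.7-fold), spp-9 (42.6-fold) and fog-3 (41.4-fold, from 1.12 ± 0.37 to 46.4 ± 13 CPM, adjusted p = 0.000341). The largest falls included F56A4.3, without a read in SIN and at 2.59 ± 0.33 CPM in N2 (at least 66.6-fold lower, adjusted p = 0.00333), the lectin gene clec-70 (from 2.36 ± 2.1 to 0.0897 ± 0.0084 CPM, adjusted p = 0.0146) and nhr-181 (14.8-fold, adjusted p = 0.000788). The neighbouring F-box genes fbxa-192, fbxa-193 and fbxa-191, of which fbxa-193 and fbxa-191 are annotated as pseudogenes, fell 21.4-fold, 17.3-fold and 14.7-fold (adjusted p = 7.18e-05, 0.000186 and 0.00388). They lie between 17637982 and 17655281 on chromosome V and may share reads. Calls were lost without SIN replicate 1 for F21F3.3 (adjusted p = 0.0526) and for alg-4, spp-9, clec-70 and fbxa-191, and the last 4 also without SIN replicate 2, with adjusted p of at most 0.117. The call of col-183 was lost without N2 replicate 1, N2 replicate 2 or SIN replicate 1 (adjusted p = 0.0686, 0.0628 and 0.0655). Folds moved as well: without N2 replicate 1 they were 47.2 for F21F3.3, 33.8 for alg-4, 21 for spp-9 and, as a fall, 41.6 for clec-70, and the ratio of F23B2.10 over 3 reads was 44.4 (15 to 217). Without N2 replicate 2, clec-70 was 9.06-fold lower, alg-4 and spp-9 at least 64.7-fold and 33.2-fold higher, and the ratios of F21F3.3 and F23B2.10 over 2 reads and 1 read were 165 (45.5 to 1370) and 152 (27.1 to 6050). The fold of col-183 was 19.4 and 65.8 without SIN replicates 1 and 2.

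Several germline lists were higher than in N2. Meiotic chromosome factors had 23 rises and 2 falls among 32, the same counts adjusted over the list alone (camera adjusted p = 1.3e-07), htp-1 rising 6.88-fold. Spindle genes had 27 rises and 7 falls among 50 (28 and 7 adjusted over the list alone; camera adjusted p = 2.1e-06), gpr-1 rising 16.3-fold and klp-16 9.22-fold. Other Argonautes and small RNA factors had 23 rises and 9 falls among 48 (23 and 12 adjusted over the list alone; camera adjusted p = 0.021, and 0.11 without N2 replicate 2), nrde-2 rising 10.8-fold. Of csr-1 and its cofactors 2 of 4 rose, adjusted over all genes or over the list alone (camera adjusted p = 0.024, and 0.057 without N2 replicate 2 and 0.054 without SIN replicate 1), ego-1 by 2.32-fold. Sperm genes had 8 rises among 33 (10 adjusted over the list alone; camera adjusted p = 4.1e-07), with spe-6 up 6.48-fold and spe-15 up 6.31-fold. None of the 24 major sperm protein genes passed, adjusted over the list alone included, although the list was called (median 2.25, camera adjusted p = 0.0083); without N2 replicate 1 its adjusted p was 0.32 and without SIN replicate 2 it was 0.12. N2 replicate 1 stood apart, with a mean relative log2 level of -2.44 against 0.22 in N2 replicate 2 and 0.44 and 1.89 in SIN. Pathogen response genes had 10 rises and 1 fall among 37 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0059), lys-2 rising 2.63-fold and lys-3 10-fold. With an estimated correlation these lists had adjusted p = 0.87, and the major sperm protein list adjusted p = 0.91. By camera, the csr-1, small RNA and major sperm protein lists were called against N2 and not against WT, a difference that was not tested. By fry, the csr-1 and small RNA lists passed against WT too (adjusted p = 0.0016 and 0.014). Because the csr-1 list includes csr-1 itself, its calls do not show that the cofactors rose as a group.

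Groups that were lower than in N2 included the zygotic genes of the early embryo, with 15 falls and no rise among 33 (19 adjusted over the list alone; camera adjusted p = 1e-04), ceh-51 falling 13.5-fold and ref-1 2.56-fold. The zygotic list stood higher in N2 replicate 1 than in N2 replicate 2, at mean relative log2 levels of 1.04 and 0.16, against -0.48 and -0.52 in SIN. Respiratory chain genes had 14 falls among 41 (23 adjusted over the list alone; camera adjusted p = 2.1e-06) and ribosomal protein genes 6 among 78 (0 adjusted over the list alone; camera adjusted p = 2e-06), with no rise in either; upper-quartile scaling left 9 and 0 falls. Histone genes had 5 falls among 26 (0 adjusted over the list alone; camera adjusted p = 0.014, and 0.057 without N2 replicate 2 and 0.071 without SIN replicate 1), and 2 falls and 1 rise with upper-quartile scaling. Cuticle genes had 2 falls among 22, dpy-10 (6.39-fold) and dpy-4 (7.4-fold), and 1 adjusted over the list alone (camera adjusted p = 0.039, and 0.48 without N2 replicate 1 and 0.16 without SIN replicate 1). Their mean relative log2 level was 1.77 in N2 replicate 1 and 0.06 in N2 replicate 2, and between -0.94 and -0.06 in the other libraries. None of 13 pharynx markers passed, adjusted over the list alone included (camera adjusted p = 0.045, and 0.24 without N2 replicate 2 and 0.33 without SIN replicate 1). With an estimated correlation each of these lists had adjusted p = 0.87.

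The other lists were not called by camera in SIN versus N2. Kinetochore genes had 11 rises and 1 fall (11 and 2 adjusted over the list alone; camera adjusted p = 0.054), P granule genes 7 and 6 (7 and 6; 0.39, with a median of -0.06 and a mean of 0.35), oocyte regulators 7 and 7 (9 and 11; 0.93, with a median of -0.11 and a mean of 0.33), cell cycle genes 9 and 11 (10 and 13; 0.76), eggshell genes 4 and 4 (4 and 6; 0.39) and proteasome genes 4 and 6 (4 and 7; 0.1). Among them hcp-3 rose 6.85-fold, glh-1 4.91-fold, cdk-1 2.81-fold and egg-4 3.37-fold, and rpn-9 and rpn-11 rose 1.48-fold and 1.37-fold. Collagen genes had 9 rises and no fall (8 and 0; 0.65, with a median of -0.18 and a camera direction of up), neuron markers 2 and 1 (2 and 0; 0.055), lipid genes 2 and 1 (0 and 0; 0.65), oxidative and xenobiotic stress genes 2 and 6 (2 and 6; 0.65) and cell death genes 3 and 3 (3 and 3; 0.53). Vitellogenins, intestine markers, muscle markers and heat shock genes had no rise and 1, 2, 1 and 1 falls (0, 2, 0 and 0 adjusted over the list alone; 0.65, 0.26, 0.65 and 0.13); with upper-quartile scaling 1 muscle marker rose and none fell. That scaling also gave 7 rises and 2 falls among P granule genes (median 0.02), 9 and 5 among oocyte regulators, 11 and 9 among cell cycle genes and 4 and 2 among proteasome genes, and medians of 0.02 and 0.03 against -0.07 and -0.05 for vitellogenins and oxidative stress genes.

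Of the SIN calls, 1280 rises and 1241 falls were shared between the comparisons with WT and with N2, and 6 genes were called in opposite directions. Independent lists of these sizes would share 231 and 272 genes. Both comparisons use the same SIN libraries, and 20 simulations of unchanged groups gave at most 2 shared calls. Those simulations had at most 9 calls against WT and 6 against N2. They thus do not show how many of the calls here are shared only because the SIN libraries are the same. The covariance of the log2 fold changes was 0.839, against a mean of 0.105 in the simulations, a difference of 0.734. In a test chosen after seeing the data, each comparison was given its own SIN library. With SIN replicate 1 against WT and SIN replicate 2 against N2, 332 rises and 98 falls were shared, where independent lists would share 13.3 and 2.58, and the covariance was 0.727. With the SIN libraries exchanged, 298 rises and 115 falls were shared, against 14.3 and 5.36, and the covariance was 0.8. The shared counts moved with single libraries: without WT replicate 1 they were 242 rises and 78 falls, without WT replicate 2 they were 309 and 129, without SIN replicate 1 they were 288 and 166, and without SIN replicate 2 they were 377 and 113, while 2219 falls were shared without N2 replicate 1.

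In SIN versus N2, 59.6% of the calls were rises with upper-quartile scaling (2202 rises and 1490 falls) and 48.2% with TMM. Without SIN replicate 1 or 2, 476 and 661 genes rose and 274 and 270 fell; without WT replicate 1 or 2, 847 and 850 fell, and without N2 replicate 2, 3314 fell. With only the 4 libraries of both groups 625 genes fell, and against a 1.5-fold change 608 rose and 235 fell.

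The WT strain was much closer to N2, with 7 genes that rose and 10 that fell among 15404, although 3091 genes had an unadjusted p under 0.05 and at most 761 did in 20 simulations of unchanged groups. Of genes named by the rule, Y38E10A.14 rose 7.94-fold, from 7.69 ± 1.3 to 61.1 ± 0.57 CPM (adjusted p = 0.00452), C08E8.3 24.9-fold to 2.97 ± 0.36 CPM (adjusted p = 0.0436) and ZC317.7 5.31-fold (adjusted p = 0.0436). The lectin gene clec-52 rose 3.64-fold, ugt-64, which overlaps C07G3.10 on the other strand, 3.57-fold, spe-6 2.96-fold and hcp-3 1.89-fold, from 92.4 ± 0.48 to 175 ± 4.4 CPM (adjusted p = 0.0145, 0.0111, 0.0473 and 0.0436). The falls were led by fbxa-193 (15.6-fold, adjusted p = 0.00452), fbxa-192 (11.6-fold, from 26.8 ± 1.7 to 2.3 ± 0.21 CPM, adjusted p = 0.00452) and nspc-16 (7.75-fold, adjusted p = 0.0436). Expression of glc-1, a glutamate-gated chloride channel gene, fell 4.41-fold, from 15.3 ± 0.89 to 3.46 ± 0.77 CPM, with 5.31 and 4.41 CPM in the SIN libraries. A 3.24-fold fall of wdfy-3 (adjusted p = 0.0436) concerns a gene that overlaps C26H9A.4 on the same strand.

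The WT calls changed with the libraries and the method used. Simulations of WT versus N2 with each gene's own spread had 15.9% false calls, and unchanged groups gave 2.3 calls on average. With any WT or SIN library left out, or with only the 4 libraries of both groups, 0 genes were called by edgeR, while folds such as these stayed close to the reported ones: over the 6 omissions log2 values were -4.09 to -3.83 for fbxa-193 (-3.96 reported), 0.89 to 0.96 for hcp-3 (0.92) and 2.83 to 3.17 for Y38E10A.14 (2.99). Without N2 replicate 1, 222 rose and 356 fell, and without N2 replicate 2, 1676 rose and 2331 fell. DESeq2 called 571 higher and 546 lower. All 17 calls were also made by DESeq2 and without either N2 library.

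Gene lists in WT versus N2 had almost no called members, yet camera called 9 as higher and 3 as lower, none with an estimated correlation (adjusted p = 0.9 for each). Meiotic chromosome factors (median log2 fold change 0.23, camera adjusted p = 2.6e-05), spindle genes (0.2, adjusted p = 3.5e-05), proteasome genes (0.18, adjusted p = 4e-05) and P granule genes (0.17, adjusted p = 0.0065) were higher by small amounts. Adjusted over the list alone, 11 meiotic, 15 spindle and 7 P granule genes rose, none of them over all genes, with 1 spindle gene falling; klp-18 was at 230 ± 0.17 CPM in WT and 137 ± 5.6 CPM in N2 (adjusted p = 0.0502). Kinetochore genes were called higher (0.16, adjusted p = 0.01, and 0.11 without N2 replicate 2 and 0.1 without WT replicate 1), with hcp-3 rising over all genes and 4 rises and 1 fall adjusted over the list alone.

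Some of the other WT calls turned with a single library. Ribosomal protein genes (median 0.14, adjusted p = 0.0019) and respiratory chain genes (0.15, adjusted p = 0.0028) had the opposite direction without N2 replicate 1 (adjusted p = 0.0058 and 0.54), and the proteasome list had adjusted p = 0.06 without it. Sperm genes (0.75, adjusted p = 0.03) included spe-6, the only member past the test over all genes, and had 2 rises adjusted over the list alone; they turned direction without WT replicate 2 (adjusted p = 0.98) and had adjusted p = 0.18 without N2 replicate 1. Major sperm protein genes (1.48, adjusted p = 0.049) turned without N2 replicate 1 (adjusted p = 0.96) or WT replicate 2 (adjusted p = 0.25), and had adjusted p = 0.082 without either SIN library. In 3 lists the levels were lower in WT: cuticle genes (median -2.36, adjusted p = 0.00047), zygotic genes of the early embryo (-0.64, adjusted p = 0.00011) and lipid metabolism genes (-0.35, adjusted p = 0.01), where 11, 0 and 3 members fell adjusted over the list alone and none over all genes. Mean relative log2 levels of the zygotic list were 1.04 and 0.16 in N2 replicates 1 and 2 and -0.12 and -0.08 in WT. Those of the major sperm protein list were lower in replicate 1 than in replicate 2 of each strain. They were -2.44 and 0.22 in N2, -1.78 and 1.67 in WT, and 0.44 and 1.89 in SIN, so an omission sets unlike replicate numbers against each other. The apical matrix gene noah-1 of the cuticle list, described after its values were seen, had 93.3 CPM in N2 replicate 1, 16.3 CPM in N2 replicate 2 and 5.89 and 5.4 CPM in WT.

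The remaining 16 lists were not called in WT versus N2, and none of their members passed over all genes. Camera adjusted p was 0.19 for csr-1 and its cofactors, 0.49 for other small RNA factors, 0.31 for oocyte regulators, 0.25 for the cell cycle, 0.85 for histones, 0.19 for eggshell genes and 0.18 for vitellogenins. It was 0.37 for intestine, 0.89 for muscle, 0.13 for pharynx and 0.36 for neuron markers, 0.93 for collagens, 0.73 for pathogen response, 0.58 for heat shock, 0.36 for oxidative stress and 0.75 for cell death. Adjusted over the list alone, 3 pathogen response genes rose and 6 fell, 2 oxidative stress genes rose and 4 fell, 3 pharynx markers fell, 3 cell cycle and 2 eggshell genes rose, csr-1 alone of its list rose, and 1 muscle and 1 heat shock gene fell. The other lists had 0. Median and test differed in sign for the small RNA factors (median -0.02, mean 0.07), histones (-0.01 and -0.18) and cell death genes (-0.02 and -0.04), where camera's direction was up, and median and mean for neuron markers (0.07 and -0.02) and heat shock genes (0.01 and -0.11).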

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

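The comparisons were recomputed under each alternative named before the data were examined; the omission of each library for the deposited gene classes and the split of the SIN libraries between comparisons were chosen only after the results were seen. Settings for normalized values, such as another pseudocount, were not run because the table holds counts. In fits without a library the lone sample of a group is assumed to vary like the other groups. For SIN versus WT and SIN versus N2, the calls shared with the reported ones numbered 3671 and 3677 with DESeq2, 3788 and 3647 with RLE scaling, and 3090 and 3379 with upper-quartile scaling. Counts within 1.5 times of the reported ones are not repeated here.

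In SIN versus WT, omitting libraries gave 252 to 3244 rises and 89 to 3375 falls around 1871 and 2051. A test against a 1.5-fold change, which asks for more, gave 480 rises and 155 falls, and using only the 4 libraries gave 3206 and 3315. Falls were 1227 with upper-quartile scaling and 1304 with at least 5 CPM in 2 libraries, which tests fewer genes. In SIN versus N2 the ranges were 476 to 2482 rises and 270 to 3314 falls around 1899 and 2043. The 1.5-fold test gave 608 and 235. Falls were 3309 with no filter beyond 1 count, 1314 with at least 5 CPM and 625 with only the 4 libraries. In WT versus N2, omission gave 0 to 1676 rises and 0 to 2331 falls around 7 and 10. DESeq2 gave 571 and 546, no filter 798 and 1419, and at least 5 CPM 21 and 40. The 1.5-fold test gave 3 and 3, upper-quartile scaling 4 and 6, and RLE scaling 14 rises. Only the 4 libraries gave 0 and 0 with edgeR, although 3091 genes had an unadjusted p under 0.05 with all libraries. Shared SIN calls ran from 242 to 1915 rises and 78 to 2219 falls, with 1947 falls without a filter. With SIN replicate 1 for WT and SIN replicate 2 for N2 they were 332 and 98, and with the SIN libraries exchanged 298 and 115, from fewer samples. Apart from the settings that test fewer genes or samples or a larger change, the cause was not tested.

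The samples of 2 groups share only a replicate number, and residuals of paired samples correlated at 0.24 for N2 and WT, 0.38 for N2 and SIN and 0.34 for WT and SIN. With that number as a block, 107 genes rose and 146 fell in WT versus N2.

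Of the gene lists, 0 were called up and 0 down in each comparison with an estimated correlation. That setting also ended calls of lists with an estimated correlation below the preset, so it does not decide for or against a list. By fry, 6 and 10 lists were called in SIN versus WT and SIN versus N2, of which 1 and 2 down. In WT versus N2 it called 2 up and 1 down. Its up calls in SIN versus WT included P granule (adjusted p = 0.0043), spindle (0.012) and meiotic genes (0.016), beside the csr-1 and small RNA lists. Omitting libraries gave 4 to 6 lists up and 4 to 5 down in SIN versus WT, 5 to 7 and 3 to 8 in SIN versus N2, and 6 to 10 and 3 to 6 in WT versus N2. Directions turned in WT versus N2 for sperm genes (adjusted p = 0.98) and major sperm protein genes (0.25) without WT replicate 2. Without N2 replicate 1 they turned for major sperm protein (0.96), ribosomal protein (0.0058) and respiratory chain genes (0.54). Over omitted libraries the adjusted p of these lists ran from 4.1e-06 to 0.98, 1e-08 to 0.96, 3e-16 to 0.0063 and 1e-08 to 0.54. With an estimated correlation the class calls of SIN versus WT were lost, at adjusted p = 0.37 for germline expressed and germline specific genes and the top quintiles by 22G reads, immunoprecipitate and both ratios, at 0.41 for the Claycomb list and the top enrichment score, and at 0.48 for the Conine list. Germline enriched genes turned direction with the block (0.73) and without WT replicate 2 (0.56) or SIN replicate 2 (0.53). Their adjusted p ran from 0.29 to 0.97, and that of the Conine list from 0.00062 to 0.13, over omitted libraries.

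Of csr-1, klp-7, unc-119 and the genes with the largest changes named by the rule, 10 of 28 in SIN versus WT, 9 of 16 in SIN versus N2 and 0 of 15 in WT versus N2 stayed on their side of the threshold under each alternative that tested them. The filter of at least 5 CPM tested only 16, 8 and 13 of them, of which 7, 6 and 0 stayed under all alternatives. Genes named only as members of lists or families were not followed one by one. At the lowest depth 3 counts are 0.0889 CPM in 1 library; bounds on folds use 3 counts over both libraries of a group.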

Other observations

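Groupings by gene name and by chromosome, and the genes named as examples, were chosen only after the results were seen, as were the tests of the ratio's denominator, of loss of slicing, of library scaling, of germline share and of sequencing depth. Intervals in brackets below come from 2000 resamplings of genes. Like the random lists, they hold the libraries fixed, so they do not cover the spread between libraries. Among 174 gene-name families with at least 8 tested genes, 2 held more rises and 8 more falls in SIN versus WT than the other genes (Fisher's exact test, Benjamini-Hochberg adjusted). That test treats genes as independent, so its p-values do not cover families whose members vary together. Of 14 nspc genes, a family of nematode-specific peptides with similar sequences, 11 rose under TMM and 12 under upper-quartile scaling (adjusted p = 3.7e-06), nspc-16 by 11.8-fold and nspc-18 by 4.31-fold. In SIN versus N2 none of the 14 passed (median 0.21, against -0.81 in WT versus N2): nspc-16 had 2.42 and 2.7 CPM in N2, 0.318 and 0.338 CPM in WT and 3.97 and 3.82 CPM in SIN, so most of its fold lies in the low WT level. Kinesin genes of the klp family had 8 rises among 15 (adjusted p = 0.012), klp-18 by 3.7-fold. Falls gathered in mitochondrial ribosomal protein genes, with 21 of 39 mrpl genes (adjusted p = 3.6e-07; 13 with upper-quartile scaling) and 12 of 27 mrps genes (adjusted p = 0.0026; 8 and 1 rise). All 8 cct chaperonin genes fell (adjusted p = 8.5e-06; 2 with upper-quartile scaling), cct-8 by 1.62-fold, as did 7 of 8 rsp splicing factor genes (adjusted p = 3e-04; 3) and 8 of 13 eif translation initiation genes (adjusted p = 0.0026; 7). The same held for 15 of 43 bath genes, 3 of which rose (adjusted p = 0.0078; 14), 14 of 44 rpl genes (adjusted p = 0.03; 2) and 8 of 19 vha proton pump genes (adjusted p = 0.041; 2). Against N2 fewer of several families fell in SIN: 7 mrpl genes (median -0.15), 4 mrps genes with 3 rises (median -0.14), 7 bath genes with 2 rises, 4 rpl genes and 2 vha genes, whereas 6 cct, 7 rsp and 7 eif genes fell, and 7 klp genes rose and 1 fell. The WT versus N2 median was 0.34 for mrpl and for mrps genes, beside -0.53 and -0.42 in SIN versus WT, so much of these falls goes with a higher WT level.

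Genes of the X chromosome, which is mostly silent in the germline, were called less often in SIN versus WT. Of 2128 X-linked genes 6.06% rose, against 13.1% of autosomal genes (odds ratio 0.428, Fisher's p = 3.3e-23), and 9.07% fell, against 14.1% (odds ratio 0.608, Fisher's p = 5e-11). With upper-quartile scaling 7.89% of X-linked and 16.3% of autosomal genes rose, and 5.31% and 8.44% fell. X-linked and autosomal genes were not matched on expression, so unequal counts were not excluded as a source of the lower call rates. Fisher's test treats genes as independent and does not measure the spread between libraries.

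Genes with more 22G reads per transcript had higher fold changes in SIN versus WT: of the 823 genes in the top quintile by the ratio to N2 RPKM, 377 rose, 43 fell and 403 did not pass. The shared denominator of the ratio and the fold change is excluded as the whole cause, since N2 RPKM does not enter SIN versus WT and the top quintile by that ratio kept a median of 0.31 (95% interval 0.27 to 0.36). So is the expression level of the genes: within quintiles of N2 RPKM, Spearman's rho of 22G reads with the log2 fold change was at least 0.46 (0.4 to 0.52). A candidate explanation is loss of CSR-1 slicing of small RNA targets. It goes with a rho of 0.53 (0.51 to 0.56) over 4114 genes and of -0.09 (-0.12 to -0.05) in WT versus N2. The top quintile by Conine 22G RNA also had more rises than falls (401 and 146). By contrast, the top quintile by enrichment score had 122 rises and 336 falls, with a median of -0.25. The whole Claycomb and Conine lists had more falls than rises with TMM scaling (1096 and 599, 1285 and 873) and more rises with upper-quartile scaling. SIN also has 4.79-fold more csr-1 RNA than WT and another strain background, which this design does not separate from loss of slicing.

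Of 151 ribosomal protein, respiratory chain and proteasome genes, 68 fell in SIN versus WT and none rose, with a median of -0.61, or 20 with 1 rise and a median of -0.47 under upper-quartile scaling. Library scaling would move all genes alike, yet neuron markers lay higher by 0.67 (0.55 to 0.8). Short and abundant transcripts are argued against as the whole cause, as the median lay at percentile 0 of random lists matched on expression and length. Those lists were low themselves, 95% of them between -0.43 and -0.27 against 0.04 for all genes, so these traits stay open as part of the cause. The 99 of the 151 genes with a 22G value differed by -0.13 (-0.2 to -0.08) from germline-specific genes of the same deciles of 22G reads per N2 RPKM. By the rule written for this test, that counts against a lower share of germline RNA as the whole cause. However, genes of these lists vary together (estimated correlations 0.88, 0.84 and 0.74). Ribosomal protein genes alone stood at mean relative log2 levels of -0.21 and 0.39 in the N2 libraries. With 2 libraries per group, so small a difference does not decide for or against that cause. The matching by decile was added after an unmatched difference of -0.28 (-0.32 to -0.25) was seen, because germline-specific genes include 22G targets that rose. A lower germline share as all or part of the cause stays open, as does a response to the loss of slicing, which was not tested.

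Cuticle genes were higher in N2 replicate 1 than in N2 replicate 2, 18 of 22 with a median log2 difference of 2.15; chosen after their values were seen, noah-1 had 93.3 and 16.3 CPM, sqt-3 82.7 and 7.32 CPM, and dpy-17 106 and 30.6 CPM. Sequencing depth is excluded, since the shift exceeded that of neuron markers by 2.21 (1.14 to 2.95). Older embryos in that sample may contribute: 30 of 33 zygotic genes were also higher, with a median of 0.69. A list of embryonic epidermis markers, fixed before its values were seen, gave a median of 0.27 (0.07 to 0.67), with 14 of 19 higher, so these markers were slightly higher too, but the interval spans both bounds set beforehand, 0.2 and 0.5, and does not decide for or against older embryos. Many of these markers are expressed in adults (median 53.5 and 49.8 CPM). Larval moulting genes were higher too (median 0.75, 9 of 13), so larvae were not excluded, although each library was made from 100 picked gravid adults, a step that would remove free larvae. Muscle markers were lower (median -1, 3 of 20 higher), and how added larvae would move them was not tested. Their mean relative log2 level was lower in replicate 1 of the other strains too, at -0.34 against 0.15 in SIN and 0.02 against 0.17 in WT. No biological explanation from the strains was tested.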
